A study of Mus musculus with 17 samples.

How the data were processed

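RNA of mouse cerebella at postnatal day 3 (strain C57BL/6) was extracted after removal of the meninges, and stranded libraries of poly-A selected RNA were made with an Illumina TruSeq kit, per the labels' protocols. The 17 samples were grouped by the genotype labels into Atr, Bax and Bak deleted (5), Bax and Bak deleted (4), Atr and p53 deleted (5) and p53 deleted (3). The authors deposited estimated counts per Ensembl transcript and sequencing lane, in a table for each of the 2 backgrounds, with 2 lanes for each sample. The submitters' processing notes name kallisto 0.42.4 and edgeR and the builds mm9 and GRCm38, without giving their roles. The estimated counts in the deposited tables need not be whole numbers, and no normalization is recorded for them. Because kallisto divides reads among transcripts of similar sequence, counts of near-identical genes depend on that division.

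The lanes of a sample were summed and the transcripts were summed to genes by GENCODE M21 (GRCm38), from which all names and coordinates come. Of 94080 transcript identifiers 92284 matched, and those that did not held 0.78% to 1.04% of the counts in the deep libraries. The sums, over 31438 genes, were rounded to whole numbers. In replicate 3 of the Atr and p53 deleted group both lane columns were identical and held 13601 counts, which were counted once. This library differed from each of the other libraries of its background by more than sampling noise (chi-square per degree of freedom 1.92 to 5.08), so it was not treated as a copy. The totals of the other 16 libraries were 42987953 to 100659645, where 1 count corresponds to at most 0.0233 CPM.

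Each background was fitted by itself with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group, robust quasi-likelihood fits and F-tests, and Benjamini-Hochberg adjustment at a threshold of 0.05. Fits contained the genotype alone, since the labels give no batch. The difference between the Atr effects was tested as an interaction over all 17 samples. Standard errors are the log2 fold change divided by the square root of the F statistic. Mean CPM and SD were taken on TMM-scaled library sizes over the deep libraries of each background, and the shallow library stayed in the planned fits. Of 535 members of the 24 gene lists, 531 matched, Cgas and Ccn3 by a synonym. The lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 24 lists, and again with an estimated correlation and with fry. The deleted genes were tested by two-sided exact permutation of CPM.

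The groups, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. Named genes are the deleted genes, the 6 largest rises and 6 largest falls per comparison among genes past the threshold with a symbol, a mean of at least 1 CPM and groups that did not overlap in the deep libraries. Added to these were up to 3 members past the threshold of each primary list (p53 targets, Sonic hedgehog and granule progenitors, S phase, G2 and mitosis, granule neurons, Atr-Chk1 and repair) and 1 of each other list by smallest p, or the member of smallest p with its values where none passed. For the interaction the rule names the 6 smallest p-values. Predicted genes without a standard symbol were passed over. Genes named outside this rule, such as the members of counts of 5 or fewer, were chosen after their values were seen. Some named genes are not reported here.

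Sequence shared between genes was measured as the percentage of a gene's 31-base words found in transcripts of another gene, and 5728 genes shared over 50%. Of the called genes, 436 without Bax and Bak, 6 without p53 and 127 of the interaction shared over 50%.

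The fits were tested on simulated counts with the real means and library sizes and 200 changed genes in each comparison. The changed genes were drawn only from the more highly expressed genes, so the recovery does not cover genes of low counts. Without Bax and Bak, 77% of 1.5-fold and 98% of 3-fold changes were recovered with 12 false calls over 17405 genes. Without p53 it was 26% and 98% with 12 false calls over 17328 genes, and for the interaction 36% and 97% with 11 false calls over 18167 genes. Alternatives were median-of-ratios and upper-quartile scaling, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, fits without robust moderation, a threshold of 0.01, tests on transcripts, all 17 samples in a joint fit, controls of 1 number series only, each library left out in turn, and the removal of genes with shared sequence. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.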

Results

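RNA was measured in whole cerebella of mice at postnatal day 3 by sequencing poly-A selected RNA. The mice carried Math1-Cre, a recombinase expressed in granule neuron progenitors, the dividing cells that give rise to the granule neurons of the cerebellum. The 17 samples formed 4 groups by genotype. In the background without Bax and Bak, the effectors of mitochondrial apoptosis, 5 samples carried loxP-flanked Atr together with loxP-flanked Bax and null Bak, and 4 controls lacked only the loxP-flanked Atr. In the background without p53, 5 samples carried loxP-flanked Atr and p53, and 3 controls carried loxP-flanked p53 alone. Atr encodes a checkpoint kinase that responds to stalled replication forks. The samples are called Atr-deleted or controls below by their genotype labels. The names of the backgrounds follow the labels too, although Bax and p53 are only loxP-flanked, so cells without Cre may keep them. The depth was 42987953 to 100659645 estimated counts in 16 libraries. The remaining library, replicate 3 of the Atr-deleted p53-deleted group, held 13601 counts in all, so that 1 count was worth 73.5 CPM (counts scaled to library size) and a gene needed 221 CPM to reach 3 counts. It stayed in the tests as planned, and means in CPM are given over the 16 deep libraries. The labels name separate samples without saying more, so p-values of single genes measure the spread between these samples, which may in part be technical. The p-values of camera for gene lists set the members against the other genes tested, so their size does not measure that spread. The shallow library's sample number is that of replicate 1 of its group with a suffix, so these 2 libraries may come from 1 mouse.

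The deleted genes were compared first. Whole-cerebellum Atr RNA did not separate the genotypes. Atr (chromosome 9, 95857597 to 95951781, GRCm38) stood at 40.7 ± 3.01 CPM (SD, n = 5) in the Atr-deleted libraries without Bax and Bak and at 43.6 ± 3.81 CPM (n = 4) in their controls, a difference within the spread (two-sided exact permutation p = 0.214). In the p53-deleted background, Atr stood at 36.7 ± 2.78 CPM (SD, n = 4) against 36.3 ± 1.03 CPM (n = 3), with a two-sided exact permutation p of 0.829 over the deep libraries and 0.714 with the shallow library. The smallest p that these designs can give is 0.00794 for 5 against 4 libraries, 0.0179 for 5 against 3 and 0.0286 for 4 against 3. Bak1, null in the germ line of the first background (chromosome 17, 27019810 to 27029009), was at 0.442 ± 0.141 CPM (SD, n = 5) in the Atr-deleted libraries there and 0.367 ± 0.153 CPM (n = 4) in the controls. In the p53-deleted background it was at 37.9 ± 4.1 CPM (n = 4) and 38.9 ± 2.06 CPM (n = 3). Bax (chromosome 7, 45461697 to 45466898) was at 33.0 ± 4.56 and 34.2 ± 2.61 CPM where it was floxed, and at 64.4 ± 7.75 and 65.1 ± 1.79 CPM in the p53-deleted background. Trp53, the gene of p53 (chromosome 11, 69580359 to 69591873), was at 70.7 ± 5.76 and 69.2 ± 4.86 CPM without Bax and Bak, and at 38.1 ± 6.74 and 36.9 ± 1.65 CPM where it was floxed. Library sizes were scaled within each background, so the levels set across backgrounds are not tested. None of these 4 genes was shown to differ between Atr-deleted and control libraries, with 8 tests over the 17 libraries giving Benjamini-Hochberg adjusted exact permutation p-values of 0.786 throughout. The shallow library was at 0 CPM for all 4 genes, which widened the spread in the tests without p53. Over the deep libraries of that background the adjusted exact permutation p-values were 0.914 throughout. The values were sums over whole genes in a tissue that also holds cells outside the Math1 lineage, and a floxed gene can keep transcripts that lack an exon, so the comparison of Atr could neither show nor exclude its deletion.

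**Figure D1:**
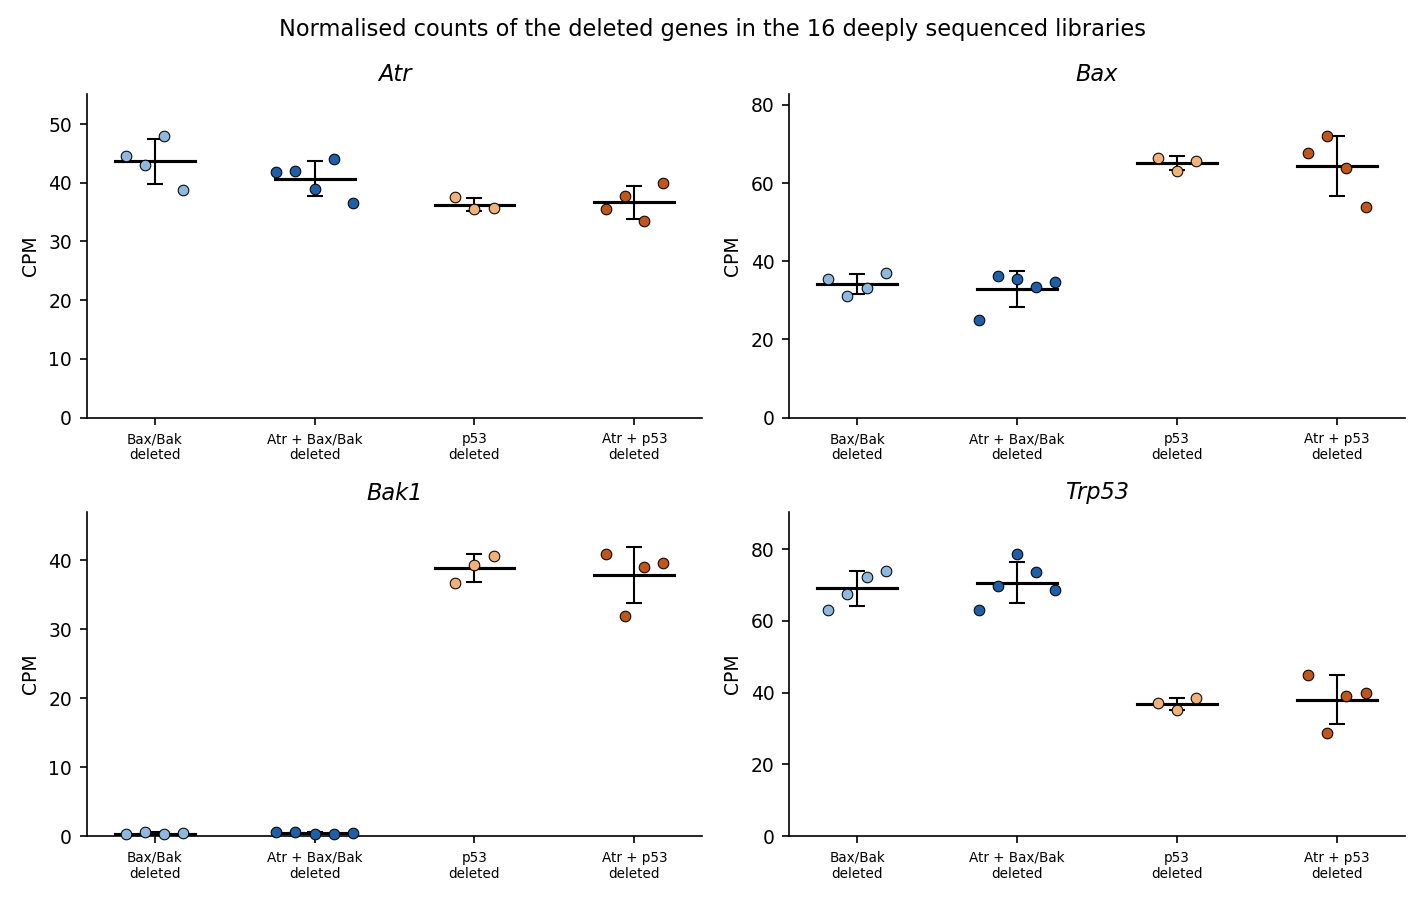
Normalised counts (CPM) of Atr, Bax, Bak1 and Trp53 in the 4 genotype groups; each point is 1 of the 16 deep libraries, and lines and bars give the mean and SD. Atr lies between 36.3 and 43.6 CPM in every group mean, while Bak1 is at 0.442 and 0.367 CPM in the Bak-null groups and at 37.9 and 38.9 CPM in the p53-deleted groups.

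The first comparison asked which RNAs changed with Atr deletion in the background of loxP-flanked Bax and null Bak. In the 5 Atr-deleted libraries, p53 target genes were higher and genes of DNA replication and mitosis were lower than in the 4 controls. Fas, a death receptor gene, rose 17-fold, to 5.53 ± 0.666 CPM (SD, n = 5) from 0.329 ± 0.0626 CPM (n = 4). Pmaip1, which encodes the BH3-only protein Noxa, rose 11.9-fold, and Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose 4.80-fold. Pclaf, a PCNA-associated factor made in dividing cells, fell to 30.4 ± 3.26 CPM from 141 ± 12 CPM. Markers of astrocytes, oligodendrocytes, microglia, interneurons and Purkinje cells were higher, as were interferon-response genes and mitochondrially encoded RNAs. None of these lists was called as a set with an estimated correlation, with adjusted p = 0.232 to 0.502 with an estimated correlation.

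By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7744 of 17405 genes changed at an adjusted p below 0.05, 3919 of them higher and 3825 lower in the Atr-deleted libraries. The balance of directions depended on scaling and on single libraries, with 3594 higher and 4060 lower by median-of-ratios size factors, 4297 and 3568 by upper-quartile scaling, and 2974 and 4361 without control replicate 2. Of the 7744, 635 rose and 130 fell by more than 2-fold. Among the 6 largest rises of the naming rule were those of Pla2g2f, a secreted phospholipase, at 5.45 ± 0.81 CPM (SD, n = 5) against 0.16 ± 0.119 CPM (n = 4), a log2 fold change of 5.12 ± 0.35 (SE, edgeR adjusted p = 3.62e-06), and of Sgca. Sgca, the alpha-sarcoglycan of muscle, was at 7.09 ± 1.0 against 0.244 ± 0.079 CPM (4.84 ± 0.23, edgeR adjusted p = 3e-07). Them5, an acyl-CoA thioesterase, rose by 4.47 ± 0.30 on the log2 scale. The 3 larger rises named by size were in genes known from the 2-cell stage of the embryo. Zscan4c had 668 counts in the Atr-deleted libraries and 0 in the controls, which makes it at least 166-fold higher against a floor of 3 counts over the control group (0.0117 CPM). Zscan4f had 1309 counts against 1, a ratio of 975 (exact 95% interval 175 to 38500), and Usp17le had 639 against 1, a ratio of 476 (85.1 to 18800). These intervals and floors cover counting error only. The Zscan4 genes and Usp17le share 48.9% to 91.1% of their 31-base words with other genes, so the split of counts within these families is uncertain.

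The largest falls included Otx1, a homeobox gene, at 1.12 ± 0.273 CPM (SD, n = 5) against 6.66 ± 2.47 CPM (n = 4), a log2 fold change of -2.58 ± 0.26 (SE, edgeR adjusted p = 2.89e-05). Pclaf fell by 2.21 on the log2 scale (SE 0.08, edgeR adjusted p = 2.18e-07). Vipr1, a receptor for vasoactive intestinal peptide, fell by 2.08 and Ooep, a gene of the oocyte, fell by 2.05. Vcp-rs had the largest fall, -7.50 ± 0.31 on the log2 scale, from 216 ± 71.7 CPM to 1.2 ± 0.449 CPM. It shares 89.5% of its 31-base words with its parent gene Vcp, and its value is uncertain for that reason.

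Of 44 measured p53 target genes, 35 rose and 3 fell, and adjusted over the list alone 35 rose and 4 fell. The risers of smallest p were Fas (log2 fold change 4.09 ± 0.17, SE), Ptp4a3 (1.34 ± 0.05) and Sesn2 (1.59 ± 0.06), each at an edgeR adjusted p of 2.18e-07. The fallers, chosen like all members of counts of 5 or fewer after their values were seen, were Rb1cc1 (-0.23), Tigar (-0.29), Sesn1 (-0.15) and, adjusted over the list alone, Triap1 (-0.15). The list as a set was called up by camera with a preset correlation (camera adjusted p = 2.42e-13), with adjusted p = 0.232 with an estimated correlation. Of 20 genes of the Bcl-2 family and caspases that are not in the p53 list, 4 rose and 9 fell over all genes and adjusted over the list alone. Bcl2l11 (0.67), Hrk (0.55) and Bcl2l2 (0.19) were among the risers, and the faller of smallest p was Bok (-0.77). The list had a camera adjusted p of 0.04, of 0.053 without Atr-deleted replicate 5 and 0.0643 with control replicates 1 and 2 only (0.0466 with 3 and 4 only), and adjusted p = 0.368 with an estimated correlation.

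All 44 S phase and replication genes fell, and all 44 also when adjusted over the list alone, among them Hells, a chromatin remodeller (-1.0), Tyms, the thymidylate synthase (-1.03), and cyclin E2, Ccne2 (-1.04). The camera adjusted p was 9.59e-25, with adjusted p = 0.232 with an estimated correlation. Of 40 genes of G2 and mitosis, 39 fell and only Ckap2 (0.21) rose, with the same counts adjusted over the list alone. The camera adjusted p was 3.33e-20, with adjusted p = 0.337 with an estimated correlation. The cyclin gene Ccna2 fell to 109 ± 13.2 CPM (SD, n = 5) from 229 ± 10.1 CPM (n = 4). Nuf2 (-1.01) and Ndc80 (-1.11), components of the kinetochore, fell too. Of 42 genes of the Atr-Chk1 pathway and DNA repair, 35 fell and 0 rose over all genes and adjusted over the list alone (camera adjusted p = 6.27e-14, and adjusted p = 0.232 with an estimated correlation). The smallest p-values were those of the nuclease gene Exo1 (-1.16), Rad54l (-0.89) and the Atr activator Topbp1 (-0.61).

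Genes of granule progenitors and granule neurons moved less uniformly. Of 19 genes of the Sonic hedgehog pathway and granule progenitors, 11 fell and 3 rose over all genes and adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.511 with an estimated correlation). Sfrp1 (-1.13), Insm1 (-0.97) and the pathway's transducer Smo (-0.39) fell, and Hhip (0.66), Gli1 (0.32) and Cxcr4 (0.25), the first a target and inhibitor of the pathway, rose. Of 33 genes of differentiating and mature granule neurons, 12 fell and 2, Astn1 (0.21) and Grin2c (1.06), rose over all genes and adjusted over the list alone. The fallers of smallest p were Stmn2 (-0.50), Gap43 (-0.54) and Dcx (-0.62), genes of young neurons. The camera adjusted p was 0.0269, with adjusted p = 0.611 with an estimated correlation. The call of granule neurons was lost without control replicate 3 (0.0656) or 4 (0.0647), without Atr-deleted replicate 1 (0.0503) and with the controls of 1 number series only, replicates 1 and 2 (0.448), but not with those of the other series, replicates 3 and 4 (0.000194). The controls of the 2 number series differed by a median of 0.28 in this list, against a change of -0.12.

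Markers of other cell types were mostly higher. Of 20 markers of astrocytes and Bergmann glia, 18 rose, with Gdf10 (1.34) at the smallest p, and only Fabp7 (-0.15) fell (camera adjusted p = 1.98e-06, and adjusted p = 0.232 with an estimated correlation). Of 13 markers of GABAergic interneurons and their progenitors, 12 rose and 0 fell, with Pax2 (0.82) at the smallest p (camera adjusted p = 5.94e-05, and adjusted p = 0.232 with an estimated correlation). The remaining called cell type lists each had a camera adjusted p between 0.000128 and 0.0431, with adjusted p = 0.502 with an estimated correlation, or 0.611 for endothelial cells and pericytes. Among them, 14 of 20 microglial markers, 14 of 19 Purkinje cell markers and 8 of 20 endothelial and pericyte markers rose, with 0 fallers in each. The markers of smallest p were Laptm5 (0.68), Gad1 (0.67) and Cspg4 (1.35) in that order of lists. Of 15 oligodendrocyte lineage markers 10 rose, again with Cspg4 at the smallest p, and only Pdgfra (-0.35) fell. The endothelial call was lost without control replicate 3 (camera adjusted p = 0.134) or 4 (0.0881), without Atr-deleted replicate 3 (0.0782) or 5 (0.057) and with control replicates 1 and 2 only (0.572), but not with 3 and 4 only (0.00176). The controls of the 2 series differed by a median of -0.24 in this list, against a change of 0.19. For these 6 lists the counts adjusted over the list alone were equal except for oligodendrocytes, with 14 rises and 1 fall. Beside these lists, 12 of 13 mitochondrially encoded RNAs rose and 0 fell over all genes and adjusted over the list alone (camera adjusted p = 1.98e-06, and adjusted p = 0.502 with an estimated correlation). The smallest p was that of mt-Co1 (0.85), which shares 63.9% of its 31-base words with other genes. Their share of the counts was 3.5% to 4.4% in the Atr-deleted libraries and 1.8% to 2.5% in the controls.

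Of 34 measured genes of interferon response and innate DNA sensing, 19 rose, with the antigen peptide transporter gene Tap1 (1.76) at the smallest p, and only Ifit2 (-0.45) fell. Adjusted over the list alone, 21 rose and 1 fell (camera adjusted p = 0.000146, and adjusted p = 0.502 with an estimated correlation). Of 16 immediate early genes, 8 rose, with Atf3 (1.30) at the smallest p, and only Egr2 (-0.61) fell, with 9 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0135, 0.06 with control replicates 1 and 2 only, 0.000674 with 3 and 4 only, and adjusted p = 0.502 with an estimated correlation). The other 8 lists were not called by camera. In the integrated stress response, 11 of 20 genes rose, with Sesn2 at the smallest p, and Psat1 (-0.21) and Mthfd2 (-0.31) fell, with 11 rises and 4 falls adjusted over the list alone, where Slc7a11 (-0.49) and Atf4 (-0.10) were added (camera adjusted p = 0.0596). Of 21 genes of inflammation and phagocyte activation, 6 rose, with Apoe (0.59) at the smallest p, and Cd63 (-0.36), Spp1 (-1.37) and Lpl (-0.37) fell (camera adjusted p = 0.277). Of 11 markers of unipolar brush cells and deep nuclei 3 rose, among them Tbr1 (0.52) and Irx3 (0.38), and of 8 erythroid markers 1 rose and 1 fell. These 3 lists had the same counts adjusted over the list alone. No marker of meninges (15 measured), choroid plexus (12) or brainstem and midbrain (13) and no sex-linked gene (4) passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p below 0.05 there were 2 such genes of the meninges and 0 in the other lists, while DESeq2 called 2 of the meninges and limma-voom 1 of the brainstem and midbrain. The members of smallest p were Ccn3 (-2.72, edgeR adjusted p = 0.0621), Otx2 (-0.32, 0.245), Hoxc4 (0.60, 0.137) and Uty (-1.07, 0.611).

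The Atr-deleted libraries of this background all carried sample names of a number series separate from those of the controls, so genotype and number series cannot be told apart. Counts of Y-linked RNA were low in 3 of the 5 Atr-deleted libraries (at most 8.44 CPM over 4 genes) and in 1 of the 4 controls (5.23 CPM), and at least 207 CPM in the others.

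**Figure D2:**
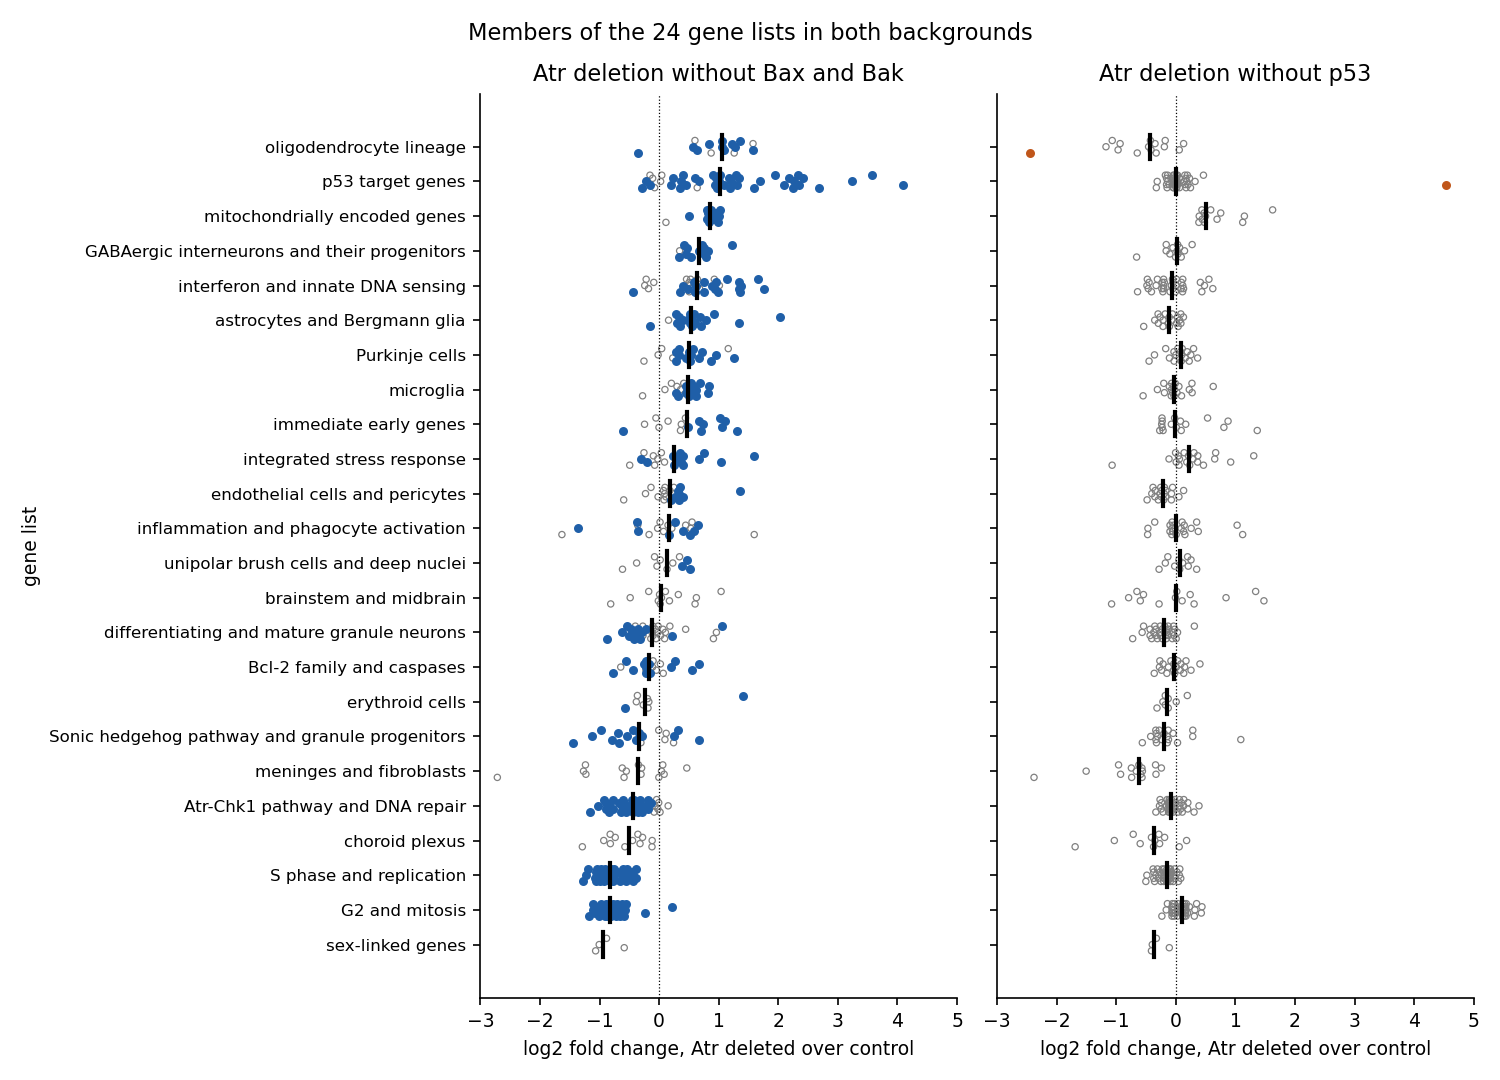
Log2 fold changes, Atr-deleted over control, of the members of the 24 gene lists in the background without Bax and Bak and in the background without p53; each point is 1 gene, filled where it passed an edgeR adjusted p of 0.05, and each black bar is the list's median. The medians of the p53 targets, S phase genes and G2 and mitosis genes are 1.02, -0.82 and -0.82 without Bax and Bak and 0.01, -0.15 and 0.10 without p53.

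The second comparison asked the same question in the p53-deleted background. There, few genes changed with Atr deletion, and the p53 target genes as a list were at a median log2 fold change of 0.01. The hormone gene Fgf21 was higher in the Atr-deleted libraries, at 3.25 ± 0.575 CPM (SD, n = 4) against 0.0285 ± 0.028 CPM (n = 3), where the controls held 6 counts in all. The histone H2B gene Hist1h2bc was at 52.9 ± 6.87 CPM against 9.97 ± 0.733 CPM, and the lectin gene Cd209c at 12.8 ± 5.58 CPM against 1.34 ± 0.337 CPM. Myelin gene Mobp was lower, at 1.33 ± 0.523 CPM against 7.22 ± 3.73 CPM.

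By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 23 of 17328 genes changed, 19 higher and 4 lower, and 1088 genes were at an unadjusted p below 0.05. Without the shallow library 8 genes changed, all higher, 7 of them among the 23; without control replicate 1, 50 genes changed, 21 higher and 29 lower. With size factors by the median of ratios the count was 15, split 14 higher and 1 lower. It was 6 with DESeq2, 2 with limma-voom and 78 in a fit over all 17 samples. Fgf21 (chromosome 7, 45613886 to 45615490) rose by 6.73 ± 0.47 on the log2 scale (SE), with an edgeR adjusted p of 1.9e-05, and of 0.00233 without the shallow library. Hist1h2bc (chromosome 13, 23684199 to 23692908) rose by 2.40 ± 0.15 (edgeR adjusted p = 7e-06 and 0.000124). Cd209c rose by 3.26 ± 0.36 (edgeR adjusted p = 0.00521 and 0.0202) and the pseudogene Olfr1372-ps1 by 2.23 ± 0.24 (0.00155 and 0.0202). Hist1h2bq rose by 2.52 ± 0.27 (edgeR adjusted p = 0.00116 and 0.0202), but shares 99% of its 31-base words with other genes. Hist1h2bc shares 33.5% (26.1% with Hist1h2bq), Cd209c 18.6% and Olfr1372-ps1 18.4%, so part of their counts also depends on how reads were divided. The other named genes passed only with the shallow library in the fit. These were Mx1, an interferon-induced GTPase (1.70 ± 0.25; edgeR adjusted p = 0.0161, and 0.121 without the shallow library), Mobp (-2.45 ± 0.37; 0.0351 and 0.126) and Sstr2, a somatostatin receptor (-0.72 ± 0.12; 0.0426 and 0.136). The 2 further genes that were lower, chosen after their values were seen, were the pseudogenes Gm16589 (-4.21) and Gm11847 (-1.33).

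Of 44 measured p53 target genes only Gdf15, which encodes a secreted stress cytokine, rose, by 4.53 ± 0.65 on the log2 scale (SE; edgeR adjusted p = 0.014, and 0.121 without the shallow library), over all genes and adjusted over the list alone. It was also among the risers without Bax and Bak (3.23). The oligodendrocyte list was called down (camera adjusted p = 0.00399, and adjusted p = 0.961 with an estimated correlation). Of its 15 markers Mobp fell over all genes, and Mobp, Pdgfra (-0.43), Mag (-1.17), Mbp (-0.97) and Ugt8a (-0.42) fell adjusted over the list alone. The integrated stress response was called up (camera adjusted p = 2.76e-05, and adjusted p = 0.961 with an estimated correlation). By edgeR, DESeq2 and limma-voom 0 of its 20 members passed over all genes, with 7 at an unadjusted edgeR p below 0.05, and 6 rose adjusted over the list alone. These were Sesn2, Aldh1l2, Chac1, Trib3, Ddit3 and Atf5, the last at a log2 fold change of 0.92 (edgeR adjusted p over all genes 0.0664).

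The other 6 lists called by camera had 0 members past edgeR's test over all genes or adjusted over the list alone, and each had adjusted p = 0.961 with an estimated correlation. DESeq2 and limma-voom also called 0, and at an unadjusted p below 0.05 there were 0 to 6 members per list, most among granule neurons. Granule neurons and meninges were called down (camera adjusted p = 0.00149 for both), as were choroid plexus (0.0223) and endothelial cells and pericytes (0.0255). G2 and mitosis (camera adjusted p = 0.0255) and mitochondrially encoded genes (0.00246) were called up. Their members of smallest p were Cntn2 (-0.57, edgeR adjusted p = 0.371), Ccn3 (-2.38, 0.637), Kcnj13 (-1.69, 0.407), Mfsd2a (-0.25, 0.851), Hmmr (0.43, 0.306) and mt-Atp6 (1.62, 0.895). The mitochondrial call was lost without Atr-deleted replicate 2, with the direction turned to down (camera adjusted p = 0.984), and without control replicate 2 (0.101). The call of G2 and mitosis was lost when any of 6 of the 8 libraries was left out, all but control replicate 1 and Atr-deleted replicate 2 (camera adjusted p = 0.0647 to 0.214). That of the choroid plexus was lost without Atr-deleted replicate 1, 3 or 5 or control replicate 2 (0.0541 to 0.48), and that of endothelial cells without control replicate 2 or 3 or Atr-deleted replicate 2 (0.0525 to 0.101). Mitochondrially encoded RNAs made up 9.0% of the counts in Atr-deleted replicate 2 and 2.1% to 3.4% in the other deep libraries of this background. Without the shallow library 9 lists were called, 6 of them the same. G2 and mitosis (camera adjusted p = 0.117) and choroid plexus (0.123) were not called. S phase genes (camera adjusted p = 1.89e-06), Sonic hedgehog genes (0.00251) and astrocyte markers (0.0479) were called down, each with adjusted p = 0.708 with an estimated correlation.

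The other 16 lists had camera adjusted p-values from 0.0715 to 0.9 and, apart from Gdf15, no member past edgeR's test over all genes. DESeq2 and limma-voom called 0 members, Gdf15 included, and 0 to 5 per list were at an unadjusted p below 0.05. Adjusted over the list alone, Atf3 (1.37, edgeR adjusted p over all genes 0.103) rose among the immediate early genes and Fcrls (0.63, 0.161) among the microglial markers. The member of smallest p was Chek1 (0.31, edgeR adjusted p = 0.624) in the Atr-Chk1 list, E2f2 (-0.50, 0.499) among the S phase genes, Sfrp1 (-0.56, 0.513) in the Sonic hedgehog list, H2-D1 (0.62, 0.473) in the interferon list and Bmf (-0.36, 0.788) among the Bcl-2 family genes. In the remaining cell type and secondary lists it was Slc4a4 (-0.36, edgeR adjusted p = 0.668) for astrocytes, Bcl11a (0.37, 0.746) for Purkinje cells, Neurog1 (-0.66, 0.44) for interneurons and Irx3 (0.21, 0.926) for unipolar brush cells. It was Slc5a7 (0.31, edgeR adjusted p = 0.862) for the brainstem, Kdm5d (-0.40, 0.947) for sex-linked genes and Lyz2 (-0.47, 0.77) for inflammation. Median, mean and camera direction differed in sign for 8 lists, none of them called: astrocytes, Bcl-2 family, brainstem, interneurons, immediate early genes, inflammation, microglia and unipolar brush cells.

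The third comparison asked whether the Atr effect differed between the backgrounds. The effect of Atr deletion on p53 target genes was higher, and that on replication and mitosis genes lower, without Bax and Bak than without p53. As sets these were called by camera at the preset correlation, with adjusted p = 0.777 with an estimated correlation for the p53 targets and adjusted p = 0.208 for the others. Cdkn1a was at 264 ± 26.6 CPM (SD, n = 5) with and 55.0 ± 5.94 CPM (n = 4) without Atr deletion in the first background, and at 74.0 ± 7.48 CPM (n = 4) and 74.1 ± 4.42 CPM (n = 3) in the p53-deleted background. In the same order, Pmaip1 was at 50 ± 12.8, 4.20 ± 0.268, 5.78 ± 1.10 and 5.18 ± 0.359 CPM. Phlda3, an inhibitor of Akt signalling, was at 32.8 ± 2.85, 6.17 ± 1.42, 6.58 ± 0.635 and 6.51 ± 0.327 CPM.

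The interaction test of edgeR's quasi-likelihood method over all 17 libraries found 2490 of 18167 genes whose Atr effect differed, 1286 of them with a higher and 1204 with a lower effect without Bax and Bak. Without the shallow library there were 2936, of which 2450 were shared, and the count was 1330 without control replicate 3 and 1421 without control replicate 2 of the p53-deleted background. Size factors by the median of ratios gave 2504 genes, split 1571 higher and 933 lower. DESeq2 found 496 genes, and tests on transcripts found 203. The genes of smallest p differed on the log2 scale by 2.26 ± 0.15 (SE) for Cdkn1a (edgeR adjusted p = 6.92e-08), 3.40 ± 0.24 for Pmaip1 (2.12e-07) and 2.39 ± 0.18 for Phlda3 (2.66e-07). Next came the adhesion gene Nectin4 (2.27 ± 0.17), the TNF receptor family gene Eda2r (2.06 ± 0.16), both at an edgeR adjusted p of 2.66e-07, and the kinase gene Map3k20 (1.40 ± 0.11, 3.39e-07). The effects on Gdf15 were not shown to differ (difference -1.33 ± 0.70, edgeR adjusted p = 0.225), nor those on Cd209c (-0.87 ± 0.37, 0.129).

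Among the lists, 29 of 44 p53 target genes had a higher effect without Bax and Bak and 0 a lower one, with 29 and 1, Tigar (-0.32), adjusted over the list alone. The camera adjusted p was 6.35e-08, with adjusted p = 0.777 with an estimated correlation, and 0.00177 with an estimated correlation without the shallow library. The effect was lower for 36 of 40 genes of G2 and mitosis and 39 adjusted over the list alone (camera adjusted p = 1.67e-21, and adjusted p = 0.208 with an estimated correlation), such as Ndc80 (-1.29). It was lower for 31 of 44 S phase genes and 40 adjusted over the list alone (camera adjusted p = 5.09e-15, and adjusted p = 0.208 with an estimated correlation), such as Ccne2 (-1.14). It was lower for 19 of 42 genes of the Atr-Chk1 list and 26 adjusted over the list alone (camera adjusted p = 0.00348, and adjusted p = 0.946 with an estimated correlation), including Chek1, the gene of the kinase Chk1 (-1.25). The effect was higher for 14 of 20 astrocyte markers and 16 adjusted over the list alone (camera adjusted p = 1.41e-07, and adjusted p = 0.208 with an estimated correlation). It was higher for 12 of 15 oligodendrocyte markers and 14 adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.847 with an estimated correlation). Interneuron markers had 9 of 13 higher and 12 adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.777 with an estimated correlation). Purkinje cell markers had 6 of 19 higher and 8 adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.847 with an estimated correlation). Among 36 interferon genes 11 were higher and only Ifit2 (-0.40) lower, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.00159, and adjusted p = 0.946 with an estimated correlation). DESeq2 called fewer members of these lists, 23 p53 targets, 25 genes of G2 and mitosis, 10 S phase genes and 2 of the Atr-Chk1 list. It called 11 astrocyte, 11 oligodendrocyte, 2 interneuron, 3 Purkinje and 1 interferon gene. For the first 4 of these lists limma-voom called 29, 36, 31 and 20. The difference was 4.01 ± 0.89 (log2, SE) for Mobp and -3.19 ± 0.76 for Fgf21 (edgeR adjusted p = 0.0104 and 0.00945). Mobp was not called without Bax and Bak (1.58 ± 0.66, edgeR adjusted p = 0.0902). Its controls there were at 11.5 and 10.5 CPM (plain library sizes) in replicates 1 and 2 and at 47 and 33.1 CPM in replicates 3 and 4. The interneuron call was lost without Atr-deleted replicate 1 of the p53-deleted background (camera adjusted p = 0.0506), and the Purkinje call without that library (0.0538) or control replicate 1 there (0.054). The other 15 lists were not called by camera, with adjusted p-values from 0.097 to 0.895. Among them 7 of 20 microglial markers had a higher effect, and 11 adjusted over the list alone (camera adjusted p = 0.115). Median, mean and camera direction differed in sign for 5 of these lists: brainstem, choroid plexus, granule neurons, erythroid cells and inflammation.

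**Figure D3:**
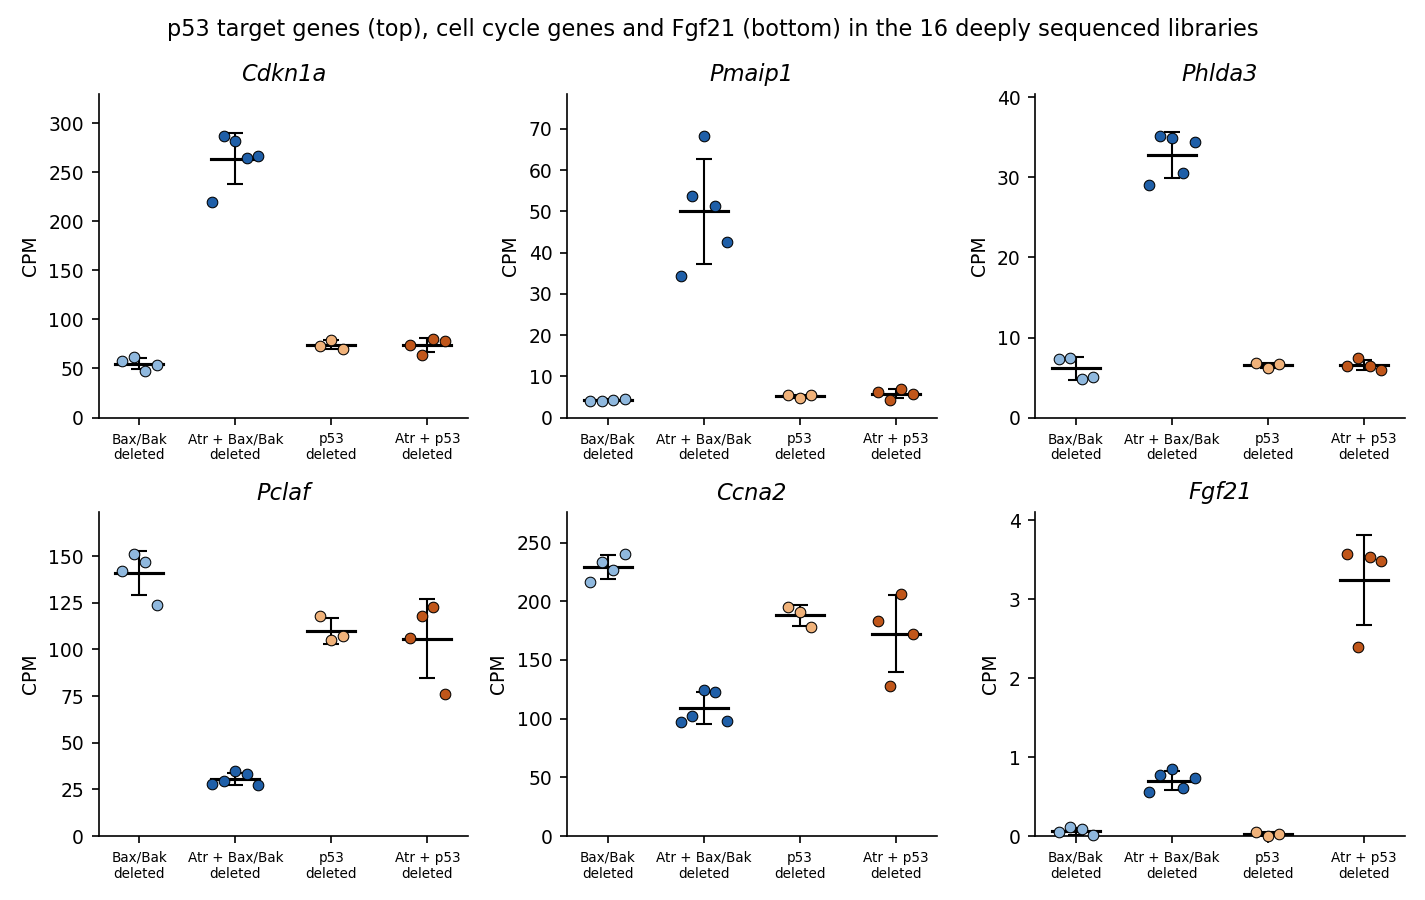
Normalised counts (CPM) of the p53 targets Cdkn1a, Pmaip1 and Phlda3, the cell cycle genes Pclaf and Ccna2, and Fgf21 in the 4 genotype groups; each point is 1 of the 16 deep libraries, and lines and bars give the mean and SD. Cdkn1a is at 264 CPM in the Atr-deleted libraries without Bax and Bak and between 55.0 and 74.1 CPM in the other group means, and Fgf21 is at 3.25 CPM in the Atr-deleted libraries without p53.

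Across the 16944 genes tested in both backgrounds, the log2 fold changes by Atr deletion correlated weakly, with a Pearson r of 0.204 and a Spearman rho of 0.129. With each library left out rho was 0.033 (without control replicate 1 of the p53-deleted background) to 0.196 (without control replicate 3 there), and 0.078 without Atr-deleted replicate 5 there. These describe genes, which are not independent replicates, and the backgrounds share no control libraries. Of the 7609 and 21 genes called in each among these, 16 were called in both, against 9.43 for independent lists (Fisher's exact p = 0.00682). Genes higher in both numbered 13 against 4.03, among them Fgf21, Gdf15, Cd209c, Hist1h2bc and Mx1; Sstr2 and Gm11847 were lower in both, against 0.68. The histone gene Hist2h2be went opposite ways, at -0.27 without Bax and Bak and 0.96 without p53.

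**Figure D4:**
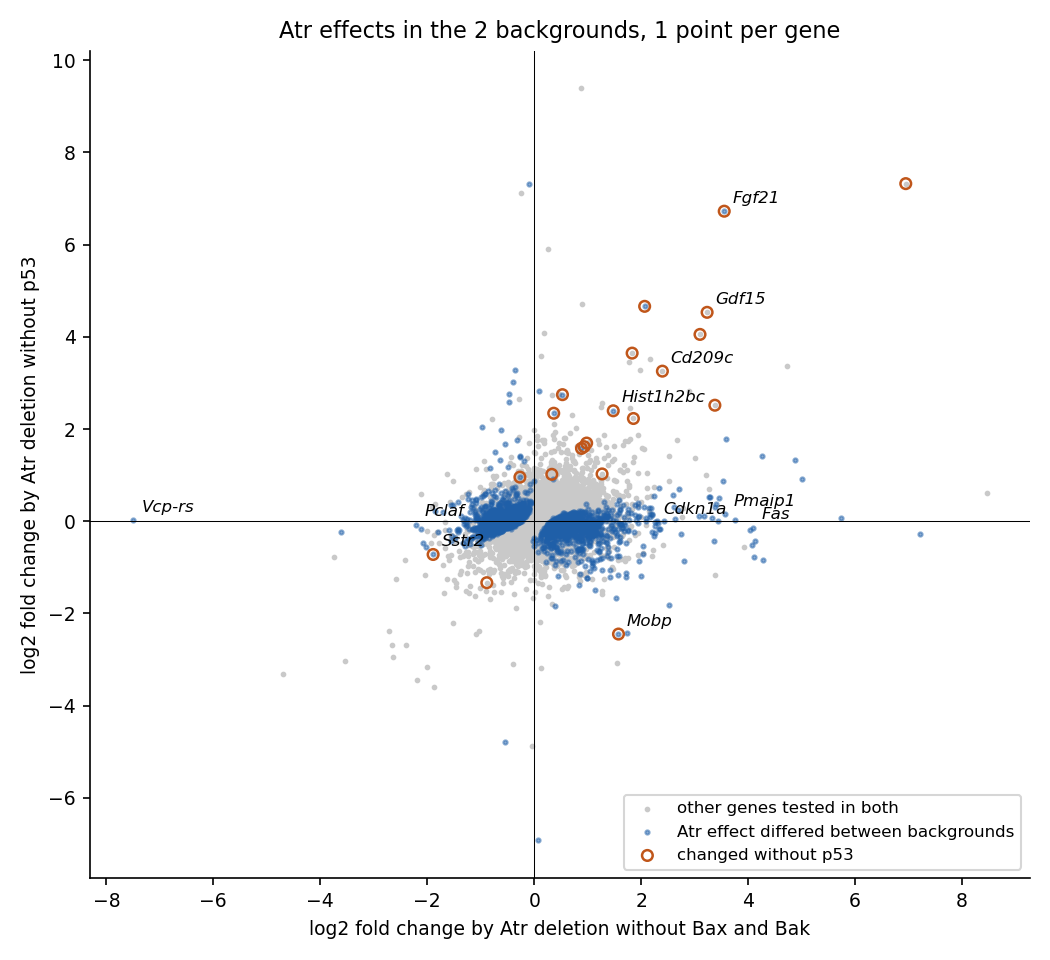
Log2 fold changes by Atr deletion without Bax and Bak (x axis) and without p53 (y axis), 1 point per gene tested in both; blue points had effects that differed between backgrounds and orange rings mark genes that changed without p53. Pmaip1, Cdkn1a and Fas lie near 0 on the y axis at 3.57, 2.26 and 4.09 on the x axis, and Fgf21 and Gdf15 are high on both axes, which correlate at a Pearson r of 0.204.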

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

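All tests of explanations and all counts over other splits of the samples in this part were chosen after the results were seen. Values were picked out here because a library stood far from the rest of its group or because the effect of Atr deletion differed between the backgrounds. Of 150 groups of libraries tested for a value standing apart, 14 had one, and chance picks out about 1 in 20.

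In the Atr-deleted libraries without Bax and Bak, replicate 1 stood apart with 25 CPM of Bax (others 33.4 to 36.3), 10.9 CPM of Ccn3 (2.1 to 4.5), 479 CPM of Gdf10 (612 to 664) and a share of 0.11% for Lars2 (0.21% to 0.25%). Replicate 3 of this group stood apart with 19.7 CPM of Tap1 (17.2 to 17.7). Among their controls, replicate 1 stood apart with 51.7 CPM of Otx2 (35.6 to 37.9) and 0.701 CPM of the Y-linked Uty (30.9 to 32.7). Replicate 2 stood apart with 323 CPM of Vcp-rs (179 to 181). Replicate 1 also had 0.0234 CPM of Zscan4f and replicate 4 had 0.0102 CPM of Usp17le, each of which is 1 count against 0 in the others. In the Atr-deleted libraries without p53, replicate 2 stood apart with 2.39 CPM of Fgf21 (3.49 to 3.57), 8.04 CPM of the Y-linked Kdm5d (40.3 to 45), 9830 CPM of mt-Atp6 (2270 to 3470) and 9.0% mitochondrially encoded counts (2.5% to 3.4%).

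The Atr effect differed between the backgrounds for 2490 genes, and for 48 of the 83 genes taken by the naming rule, by the interaction in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 100 splits of the samples the real split alone gave 2490, and the highest other gave 71. These splits exchanged Atr labels in both backgrounds at once, which also breaks up the Atr effect within each. They therefore cannot exclude chance for a difference between the backgrounds alone. Among p53 target genes and genes of the largest rises, the effect without Bax and Bak was higher on the log2 scale by 5.12 for Pla2g2f, 4.83 for Them5, 4.20 for Fas, 3.59 for Sgca, 3.40 for Pmaip1, and 2.39 for Phlda3. It was higher by 2.27 for Nectin4, 2.26 for Cdkn1a, 2.06 for Eda2r, 1.40 for Map3k20, 1.32 for Ptp4a3 and 1.11 for Sesn2. Among markers of cell types and interferon and inflammation genes, it was higher by 4.01 for Mobp. The rise of Mobp without Bax and Bak was itself not called (edgeR adjusted p = 0.0902). The effect was higher by 1.95 for Tap1, 1.23 for Gdf10, 1.21 for Cspg4 and 1.11 for Neurog1. Smaller differences were 0.86 for Laptm5, 0.85 for Slc4a4, 0.71 for Pax2, 0.67 for Apoe, 0.60 for Gad1 and 0.59 for Mfsd2a. It was lower for genes of replication, mitosis and repair, by differences of -2.16 for Pclaf, -1.29 for Ndc80, -1.25 for Chek1, -1.14 for Ccne2 and -1.07 for Hmmr. Smaller ones were -0.97 for Nuf2, -0.95 for Ccna2, -0.92 for Hells, -0.89 for Tyms, -0.84 for Exo1, -0.79 for Rad54l, -0.71 for E2f2 and -0.49 for Topbp1. The remaining lower effects differed by -7.55 for Vcp-rs, -3.19 for Fgf21, -1.63 for Vipr1, -1.19 for Sstr2, -0.93 for Hist1h2bc, -0.58 for Atf5, -0.53 for Gap43, -0.51 for Bok and -0.47 for Dcx.

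The rise of p53 target genes without Bax and Bak was weighed first. Reads shared between related genes are argued against by the 38 members that share at most 5% of their 31-base words, of which 33 rose, with a median log2 fold change of 1.12. A lower share of granule lineage cells would raise p53 targets no more than the markers of other cell types. The p53 targets exceeded the mean of 5 such lists by 0.61 on the log2 scale (SD 0.11 over 5 Atr-deleted and 0.03 over 4 control libraries, two-sided exact permutation p = 0.00794, adjusted over 3 such tests 0.0238). They did not exceed the oligodendrocyte list, whose median log2 fold change was 1.06 against 1.02 for the p53 targets. The gap therefore argues against a lower share only as far as the mean of those 5 lists goes. The number series of the sample names coincides with the genotype and cannot be told apart from it, although the 2 series among the controls differed by a median of only 0.03. A response of p53 to Atr deletion is a biological hypothesis that the smaller effect in the p53-deleted background would be consistent with.

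The rise of glial and neuronal markers without Bax and Bak came next. A lower share of granule lineage cells stays open for the Purkinje, interneuron, astrocyte and microglial lists, which exceeded the endothelial list, the called list of smallest rise, by 0.34 (SD 0.12 over 5 and 0.13 over 4 libraries, two-sided exact permutation p = 0.0159, adjusted 0.0239), since the controls of the 2 number series differed by 0.23 in the same gap. It stays open too for the oligodendrocyte list, which exceeded the mean of 5 others by 0.5 (SD 0.37 and 0.4, exact permutation p = 0.0952). The number series of the sample names also stays open, since its controls differed by a median of 0.68 for oligodendrocyte markers. A loss of dividing granule progenitors, another share of each cell type or a changed expression within these cells may each contribute, and the design does not separate them.

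The pseudogene Vcp-rs was at 179 to 323 CPM in the controls without Bax and Bak and at most 1.95 CPM in every other deep library. Its sum with the parent gene Vcp was 618 ± 36.6 CPM (SD, n = 5) against 566 ± 10.4 CPM (n = 4), a ratio of 1.09, so that reads divided otherwise between the copies may account for it. For the pseudogene Gm15459, chosen after its values were seen and at 412 to 907 CPM in the Atr-deleted libraries without Bax and Bak against 3.39 to 4.19 CPM in their controls, the sum with its parent Hspa8 had a ratio of 0.688, which leaves shared reads open. Although on and off followed the genotype there, Atr deletion as the whole cause is argued against, since in the p53-deleted background 2 libraries, 1 Atr-deleted and 1 control, were at 5.11 CPM or less and the other 5 at 550 CPM or more. The sum with Hspa8 was 2140 and 2470 CPM in these 2 libraries and 2040 to 2530 CPM in the other 5. In that background the sum therefore did not separate libraries with and without the signal. That both groups there, 2 of 2, held libraries of both kinds is consistent with a strain variant against the reference that segregates among the mice.

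Of 100 splits of the libraries without Bax and Bak, the real split alone gave as many as 7744 genes, and the highest other gave 3925. A chance split of single libraries is thus argued against. Chance between sets of mice cannot be excluded, since the real split is also that of the number series. The splits with 3925 and 3913 genes each set all 4 controls and 1 Atr-deleted library together. The 1 further drawn split of this form gave 0 genes. For the 23 genes without p53 chance could not be excluded, since 3 of the 56 splits gave as many. The highest others gave 348 and 73, several times the real count, for reasons that were not tested. The split with 73 is 1 of 5 that set the 2 controls of the other number series and 1 Atr-deleted library apart from the rest, as near to the number series as groups of these sizes allow. The other 4 of these gave 18, 9, 1 and 0 genes, fewer than the real 23, so the number series alone does not mark the splits that call many genes. The number series that holds both genotypes leaves only 1 control, control replicate 1, so no count of genes is given within it. The Lars2 share of this library was 0.23%, against 0.67% to 0.93% in the other deep libraries of its background. Its unmatched identifiers held 0.79% of the counts, against 0.97% to 1.04%. It therefore cannot be assumed to vary like the other libraries. Chance could not be excluded for the number of called gene lists in any comparison. Without Bax and Bak, splits that called 0 genes still gave up to 17 lists, so this count does not judge any single list. Of 100 splits, 12 gave as many as the real 16 without Bax and Bak (highest other 17). Without p53, 3 of 56 gave as many as the real 8 (highest other 8), and for the interaction 18 of 100 gave as many as the real 9 (highest other 13).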

How the results depend on the processing

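The comparison of gene lists between backgrounds, the removal of genes with shared sequence and the fits without both the shallow library and another library were chosen after the data were seen. No named gene past the threshold changed direction, but some called gene lists without p53 did. Fry put G2 and mitosis (adjusted p = 0.654) and the integrated stress response (0.959) down where camera called them up, and mitochondrially encoded genes turned down without Atr-deleted replicate 2 (camera adjusted p = 0.984, against 6.24e-05 up without control replicate 1). In the interaction, fry put the Atr-Chk1 list up (adjusted p = 0.811) where camera called it down. Once the shallow library was left out, fry called this list (adjusted p = 0.000539), at a median log2 difference of -0.40. The fry adjusted p of the p53 targets in the interaction was 0.426 with that library and 3.85e-09 without it. In the p53-deleted background its removal left the integrated stress response at a fry adjusted p of 0.397, and G2 and mitosis at 0.852. Without Bax and Bak, the count of 7744 genes stayed between 5331 (threshold 0.01) and 8162 (DESeq2), and 6704 to 7760 with each library left out. Without p53, 23 genes became 15 with median-of-ratios size factors, 37 without a filter, 11 at a mean of at least 1 CPM, 6 with DESeq2 and 2 with limma-voom. It was 78 in a fit over all 17 samples, 9 at a threshold of 0.01 and 7 on transcripts. The count was 50 with the controls of 1 number series, and 8 when the replicates with a shared sample number were averaged. Leaving out each library gave 8 (Atr-deleted replicate 3, the shallow library) to 50 genes (control replicate 1). Without the shallow and the mitochondria-rich library the count was 2, and without the shallow library and control replicate 1 it was 13. The 2490 genes of the interaction became 496 with DESeq2, 940 at a threshold of 0.01 and 203 on transcripts, and 1330 (without p53 control replicate 3) to 2937 with each library left out, with 1421 without p53 control replicate 2. The causes were not tested, except that fewer samples, another threshold and fewer genes belong to the alternatives themselves. With an estimated correlation camera called 0 lists in each of the 3 comparisons. Fry called 18 lists without Bax and Bak, 0 without p53 and 1 for the interaction. Without the shallow library fry called 11 lists for the interaction and camera with an estimated correlation called 1. With libraries left out camera called 14 to 17, 4 (without control replicate 2) to 11, and 8 to 11 lists. The Pearson correlation of 0.204 was 0.237 over genes past 0.05 in either background and 0.165 to 0.233 with each library left out. On single transcripts of the deleted genes, 1 of 15 tests over both backgrounds passed unadjusted, a Trp53 transcript at 4.97 ± 1.16 CPM (n = 5) against 2.02 ± 1.19 CPM (n = 4) without Bax and Bak (two-sided exact permutation p = 0.00794, Benjamini-Hochberg adjusted 0.119). Among named genes, Hist1h2bc stayed past the threshold in every alternative without p53, while Sstr2 lost it in 15 of 22, Mobp in 12 of 22, Mx1 in 8 of 22 and Gdf15 in 6 of 21. Of the values of named genes without Bax and Bak, 987 kept their side of the threshold, 1 lost and 6 gained it. Depth limits the p53-deleted background least in its 7 deep libraries; in the shallow library only genes above 221 CPM reach 3 counts. No paired analysis was possible because replicate numbers follow accession order and do not pair samples.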

Other observations

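The gene groups, tests and values in this part were all chosen after the data were seen. Genes of cholesterol synthesis and uptake were lower after Atr deletion without Bax and Bak. Of 24 such genes, 21 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0 rose. Idi1, an isomerase of the isoprenoid steps, fell by 0.84 on the log2 scale, Stard4, a cholesterol carrier, fell by 0.66 and Sqle fell by 0.50, while Lss, Tm7sf2 and Dhcr7 did not pass. The group was chosen after falls of its members were seen, so the camera p of 1.02e-09 for the set, and of 0.0138 with an estimated correlation, is no separate evidence. Between the backgrounds the effect was lower for 9 of the 24, and the set was not called with an estimated correlation (camera p = 0.332, fry p = 0.945). In the p53-deleted background 0 of the 24 genes passed by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p below 0.05, and camera with a preset correlation gave a p of 0.0537 for the set.

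Of 59 measured genes of the histone clusters, 5 were among the 19 genes that rose after Atr deletion without p53, Hist1h2bc, Hist1h2bq, Hist1h1c, Hist1h2ah and Hist2h2be. The group was chosen for these risers, so Fisher's exact p of 4.31e-09 for their number is no separate evidence. As a set the camera p was 6.31e-06 with the preset correlation, 0.441 with an estimated correlation, and the fry p was 0.915. Hist1h2bq and Hist1h2ah share 99% and 91.2% of their 31-base words with other genes, so their counts are uncertain. Without Bax and Bak 18 of 44 histone genes rose and 5 fell, Hist1h2ag, Hist1h2ap, Hist1h4c, Hist1h3c and Hist2h2be. Fgf21 and Fut1, which rose by 4.66 on the log2 scale without p53, are neighbours on chromosome 7, and Gm7489 was at 0 in the p53-deleted controls and at 0.33 ± 0.0612 CPM (SD, n = 4) with Atr deletion.

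The genes of the 2-cell embryo were followed further as a hypothesis of induction in the Atr-deleted cerebellum without Bax and Bak. The set was chosen because some members were among the largest rises, and its 12 members that passed the expression filter mostly did so by their counts in the Atr-deleted libraries, so that their rise is no separate evidence. The summed level of 23 members was 15.9 ± 7.14 CPM (SD, n = 5) against 1.09 ± 0.155 CPM (n = 4), 14.6-fold higher. The risers lie on 3 chromosomes, which argues against 1 local variant as the cause. In the p53-deleted background the sum was 1.58 ± 0.374 CPM (n = 4) with Atr deletion against 1.13 to 1.44 CPM in the 3 controls, a ratio of 1.26 (two-sided exact permutation p = 0.2, smallest possible 0.0286). Of the 12 members 0 passed the interaction by edgeR, DESeq2 or limma-voom and 2 were at an unadjusted p below 0.05, and most had few or 0 counts in the p53-deleted background. As a set, the interaction had a camera p of 3.63e-32 with the preset correlation and 0.000136 with an estimated correlation, and a fry p of 6.78e-07. Since the set was chosen for its rises, these p-values are no separate evidence. An induction that needs p53 would be consistent with the level of 1.58 CPM, but the number series of the sample names differs between the genotypes without Bax and Bak and stays open as a cause.

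Some values describe libraries and not genotypes. RNA of the choroid plexus gene Ttr ranged from 0.37 to 3610 CPM without Bax and Bak and from 15.2 to 338 CPM without p53. Summed Y-linked RNA of 4 genes was at most 8.44 CPM in Atr-deleted replicates 1, 2 and 3 and 5.23 CPM in control replicate 1 without Bax and Bak, 8.43 CPM in Atr-deleted replicate 2 without p53, and at least 169 CPM in the other deep libraries.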
